A study of Mus musculus with 26 samples.

How the data were processed

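The series holds 26 mouse RNA-seq libraries, each from 1 cell. Astrocytes of the postnatal spinal cord, sorted with magnetic beads, were transduced in culture with the proneural transcription factor Ascl1 or Neurog2. After 3 to 4 weeks single cells were recorded by patch clamp, drawn into the recording pipette and amplified with SmartSeq2, a full-length cDNA method without molecular identifiers, per the labels' protocols. The labels give each cell a factor (Ascl1, Neurog2, DsRed or Control) and an electrophysiological class (firing, immature or no). Together these make 8 groups. Ascl1 has 4 firing, 5 immature and 2 no cells. Neurog2 has 7 firing, 3 immature and 1 no cell. DsRed has 3 cells and Control 1 cell, all of the class no. DsRed is a red fluorescent protein, used here as the control without a factor. The labels do not say how the Control cell differs from the DsRed cells, so it was kept apart from them.

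The values are a signal that the authors deposited as 1 gene-level table of normalized counts, with 55487 gene symbols and a column for each cell. The reads were aligned with STAR to the mouse genome build GRCm38, per the submitters' processing notes. The annotation, the read counter, its handling of reads that map to several places, any filter and the normalization method are not given in the sources used here. In each column of the deposited signal, every value was a whole multiple of the smallest nonzero value, within 0.01 of a whole number for 100% of values in every cell. The values are therefore read counts divided by 1 factor per cell, and dividing by the value of 1 read gave the reads back. The normalized values do not add up to the same total in every cell, so results were also computed after rescaling. The symbols of 53292 genes matched the GENCODE M21 annotation of GRCm38, from which gene coordinates were taken. Drgx was looked up under its older symbol Prrxl1.

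A cell is not an independent replicate of a culture, and the labels name no animal or culture for any cell. Each group therefore counts as 1 sample. No p-value, standard error or number of changed genes was computed, and no count model was fitted to the recovered reads. Errors are SDs over cells, which measure the spread from cell to cell. Expression was compared as log2(normalized count + 1), with a pseudocount of 1, as the difference of group means, which understates differences for genes of low value. Differences are set against the pooled SD, the root of the mean of both groups' variances. A gene counts as detected in a cell at 5 or more normalized counts. Shares of cells have exact Clopper-Pearson 95% intervals. These intervals treat the cells of a group as independent draws. Because cells are not replicates, the intervals cover the error of counting so few cells and not differences between cultures. Reads without molecular identifiers are also not independent molecules.

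Before the data were examined, 5 comparisons, 26 gene lists and a rule for naming genes were fixed. The comparisons were Ascl1 with DsRed cells, Neurog2 with DsRed cells (all classes together in both), Ascl1 firing with Neurog2 firing cells, and firing with immature cells of each factor. Named genes were the 10 genes with the largest positive and the 10 with the largest negative difference per comparison. They had to be above 0 in at least 75% of the cells of the higher group, with a mean of at least 20 there. Predicted gene models, clone-named genes, mitochondrial genes and ribosomal protein genes were left out. In addition, 2 to 4 members with the largest differences were named per list. Gal, Lhx3, Slc6a1, Th, Foxj1 and Chil1 were counted per cell, at 5 and at 1000 normalized counts, only after their values had been seen.

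The lists were pan-neuronal genes, presynaptic genes, sodium channels, potassium channels, calcium channels, vesicular glutamate transporters, GABA and glycine transmission genes, genes of other transmitters, glutamate receptors, GABA and glycine receptors, astrocyte genes, reactive and mesenchymal glial genes, genes of the proneural cascade, V2 interneuron genes, genes of other spinal neuron types, posterior Hox genes, forebrain genes, proliferation genes, glycolysis genes, cholesterol synthesis genes, oligodendrocyte lineage genes, microglia genes, vascular and fibroblast genes, ependymal genes, stress and immediate early genes, and mitochondrial transcripts. A cell's score for a list is the mean log2(normalized count + 1) over all members. To describe how far a list stands apart, the median difference of its members detected in any cell was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes these libraries and is not a test.

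The procedure was tested on simulated data for the comparison of Ascl1 with DsRed cells, with 17026 genes and a log2 change of 3 given to 100 genes in each direction. The recovered median difference was 2.92 for the genes set higher and -3.06 for those set lower, and -0.12 for unchanged genes. All planted genes (100%) had the planted sign. Planted and unchanged genes were taken only from genes with many expected reads, and no loss of transcripts was simulated. Recovery was therefore nearly certain. The simulated cells were also brought to the same total, while the reported differences use the deposited values. The simulation therefore leaves out the difference in scale between Ascl1 and DsRed cells. The value of -0.12 does not show where unchanged genes lie on the deposited scale. The simulation checks the calculation on rescaled values and does not show how well genes of low value or with many zeros are recovered.

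Alternatives fixed beforehand were pseudocounts of 0.1 and 10, rescaling each cell to a total of 1000000, medians over cells, only genes with a mean of at least 10 (9790 genes), leaving out cells in which few genes had a read (fewer than 2713), firing cells only, adding the Control cell to the DsRed cells, leaving out each cell in turn in groups of up to 5 cells, and detection above 0 or at 50. Thinning the reads of each cell to 700000, and leaving out the 2 cells in which the labelled factor was not detected, were added after the data had been seen. Rescaling moved the median difference over the 9790 genes by 0.22 for Ascl1 against DsRed cells (from 0.28 to 0.50) and by 0.21 for Neurog2 against DsRed cells (from 0.24 to 0.45). In the other comparisons it stayed at 0.00. Differences from DsRed cells are given on the deposited scale and include this difference in scale. For genes with reads in most cells it is larger than these medians, because a value of 0 does not change on rescaling. The mean summed value was 1.19e+06 in Ascl1, 1.22e+06 in Neurog2 and 1.91e+06 in DsRed cells. The reactive and mesenchymal difference for Ascl1 was -5.64 before and -5.05 after rescaling. Small differences from DsRed cells may therefore reflect scale alone.

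Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.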

Results

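Gene expression was measured in 26 single cells from cultures of mouse spinal cord astrocytes, to which Ascl1, Neurog2 or the red fluorescent control DsRed had been delivered. Each cell had first been recorded by patch clamp and was labelled firing, immature or no. The cultures were kept for 3 to 4 weeks in a serum-free medium with growth factors added every 3 days. Of the cells, 11 had received Ascl1 (4 firing, 5 immature, 2 no) and 11 Neurog2 (7 firing, 3 immature, 1 no). The 3 DsRed cells and the 1 Control cell all had the class no. Values are normalized counts, and ± gives the SD over cells. There were no replicate cultures that the labels identify, so differences describe these cells and no test was made.

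The libraries held between 721017 and 2141987 reads. The mean was 1.66e+06 reads in Ascl1 cells, 1.79e+06 in Neurog2 cells and 1.52e+06 in DsRed cells, and the Control cell had 1108418 reads. A median of 5426 genes had at least 1 read per cell, with a range from 2058 to 8206. The mean was 5420 ± 1508 genes in Ascl1 cells, 5224 ± 1899 in Neurog2 cells and 4841 ± 1330 in DsRed cells. The shallowest library had the most genes with a read. Mitochondrial transcripts took 0.164% to 4.96% of the reads. The ribosomal RNA gene listed as CT010467.1 took 0.498% to 30.9%, with the highest share in the Control cell. Across genes, Pearson's r between any 2 cells lay between 0.228 and 0.674. Its median was 0.497 over 231 pairs of factor cells and 0.364 over 88 pairs of a factor cell with a DsRed or Control cell. Genes are not independent replicates, and these coefficients only describe likeness.

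Reads of the delivered factors marked the cells as labelled, with 1 exception for each factor. Ascl1 (chr10 87490819 to 87493660, minus strand, GRCm38) had a mean of 2590 ± 2208 normalized counts in Ascl1 cells. It was detected in 10 of 11 Ascl1 cells (90.9%, 95% interval 58.7% to 99.8%). It did not exceed 1.18 in any other cell. Neurog2 (chr3 127633135 to 127635631, plus strand) had a mean of 912 ± 1040 in Neurog2 cells and was also detected in 10 of 11. Its highest value in an Ascl1 cell was 6.91, and it was 0 in the DsRed and Control cells. The exceptions were Ascl1 no replicate 1, with 0 for Ascl1, and Neurog2 firing replicate 2, with 0.709 for Neurog2. Reads of the delivered and of the cell's own gene cannot be told apart in this table.

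The first comparison addressed what distinguishes Ascl1 cells from cells with DsRed alone. Pan-neuronal genes, which code for the neuronal cytoskeleton, RNA-binding proteins and growth proteins, were higher in Ascl1 cells. Their score was 6.92 ± 1.23 against 1.13 ± 0.32, a difference of 5.79, and 18 of 18 members were higher. Each of the 11 Ascl1 cells scored above every DsRed cell. Snap25 (chr2 136713453 to 136782428, plus strand), part of the vesicle fusion machinery, averaged 2093 ± 1010 in Ascl1 cells and 0.394 ± 0.682 in DsRed cells. The microtubule gene Mapt averaged 1258 against 0.551, and Tubb3 averaged 654 ± 738 against 0. Presynaptic genes scored 5.07 ± 1.62 against 1.05 ± 0.75, a difference of 4.01, with 15 of 15 members higher and 10 of 11 cells above every DsRed cell. Cplx1, a regulator of vesicle release, averaged 1162 ± 923 against 0.394. Both lists lay at percentile 100 of matched random lists.

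Scores for genes of excitability and of receiving input were also higher in Ascl1 cells. Sodium channels scored 2.22 ± 1.30 against 0, with 8 of 9 members higher, and Scn2b averaged 292 ± 385. With all members at 0 in DsRed cells, none could be lower. The score difference was 1.5 for potassium channels, where Kcnc1 averaged 122 against 0, and 1.35 for calcium channels. It was 1.51 for glutamate receptors and 1.09 for GABA and glycine receptors. The AMPA receptor gene Gria2 averaged 888 ± 508 against 0.551, whereas Gria3 averaged 5.78 against 319 ± 504 and was lower in Ascl1 cells. Glrb, the glycine receptor beta subunit, averaged 320 ± 308 against 0.315. Among matched random lists, the median members lay at percentile 96.2 for sodium channels, 99.8 for potassium channels, 99.8 for calcium channels and 91.6 for glutamate receptors. For GABA and glycine receptors it lay at percentile 53.3, with a median difference of 0.12. There 7 of 13 members were higher and 6 were listed at 0 in both groups. The median was taken over the 10 members detected in any cell, and it was low because some of the higher members barely differed. By the mean of its members that list lay at percentile 99.8, and 11 of 11 Ascl1 cells scored above every DsRed cell.

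Astrocyte genes were lower in Ascl1 cells, with a score of 1.53 ± 0.83 against 6.57 ± 1.54. The difference was -5.04, and 17 of 19 members were lower. The gap junction gene Gja1 averaged 0.208 against 1498 ± 563, and the glial transcription factor gene Sox9 averaged 6.03 against 1478. Reactive and mesenchymal genes scored 2.21 ± 1.52 against 7.84 ± 1.31, a difference of -5.64, with 10 of 11 members lower. Vim (chr2 13573927 to 13582826, plus strand), an intermediate filament gene, averaged 185 against 12966 ± 1134. The hyaluronan receptor gene Cd44 averaged 0.592 against 2029. Each Ascl1 cell scored below every DsRed cell for both lists, which lay at percentile 0 of matched random lists. Stress and immediate early genes differed by -2.56, with Atf3 at 25.1 against 1331 ± 614 and Junb at 95.3 against 1801. Ependymal genes differed by -2.0, and Foxj1, a regulator of motile cilia, averaged 504 ± 636 in DsRed cells.

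Developmental and metabolic lists went in both directions. The difference was 0.80 for the proneural cascade, in which Sox11 was higher while Btg2 and Sox4 were lower in Ascl1 cells. It was 0.58 for V2 interneuron genes, where Lhx3 was the only member with a large difference. It was 0.26 for genes of other spinal neuron types, 0.77 for posterior Hox genes, 0.03 for forebrain genes and 0.66 for proliferation genes, the last mainly from the replication genes Mcm2 and Pcna. The Hox difference was 0.27 when DsRed replicate 3 was left out. The difference was -0.64 for glycolysis genes, where Hk2 averaged 0 against 208, and 1.17 for cholesterol synthesis genes, where Insig1 averaged 138 against 0. It was -0.21 for oligodendrocyte lineage genes, 0.01 for microglia genes, 0.01 for vascular and fibroblast genes, and 0.47 for mitochondrial transcripts. The lists for GABA and glycine transmission, other transmitters and vesicular glutamate transporters differed by 1.33, 0.17 and 0.00. Of these lists, those for the proneural cascade, V2 interneurons, other spinal neuron types and proliferation exceeded the pooled SD.

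Among 1235 candidate genes, the largest positive differences between Ascl1 and DsRed cells were those of Snap25, Snca, Ascl1, Mllt11, Mapt, Gal, Stmn3, Pkib, Bex2 and Septin3. Snca, a presynaptic gene, averaged 2037 ± 559 in Ascl1 cells, and Mllt11 averaged 2296 ± 956. Gal (chr19 3409915 to 3414544, minus strand), which codes for the neuropeptide galanin, averaged 29778 ± 29309 against 19 ± 22.2, a log2 difference of 9.33. Among 1106 candidates, the largest negative differences were those of C3, Steap4, Ifitm3, Plekhb1, Hbegf, Cp, Cebpd, Sdc4, Lcn2 and Tmem100. The complement gene C3 averaged 12.6 in Ascl1 cells and 16706 ± 14799 in DsRed cells, a difference of -12.49. The metalloreductase gene Steap4 averaged 0.141 against 5075 ± 1997, a difference of -12.11. These genes have the most extreme differences of many, taken from only 3 DsRed cells.

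**Figure D1:**
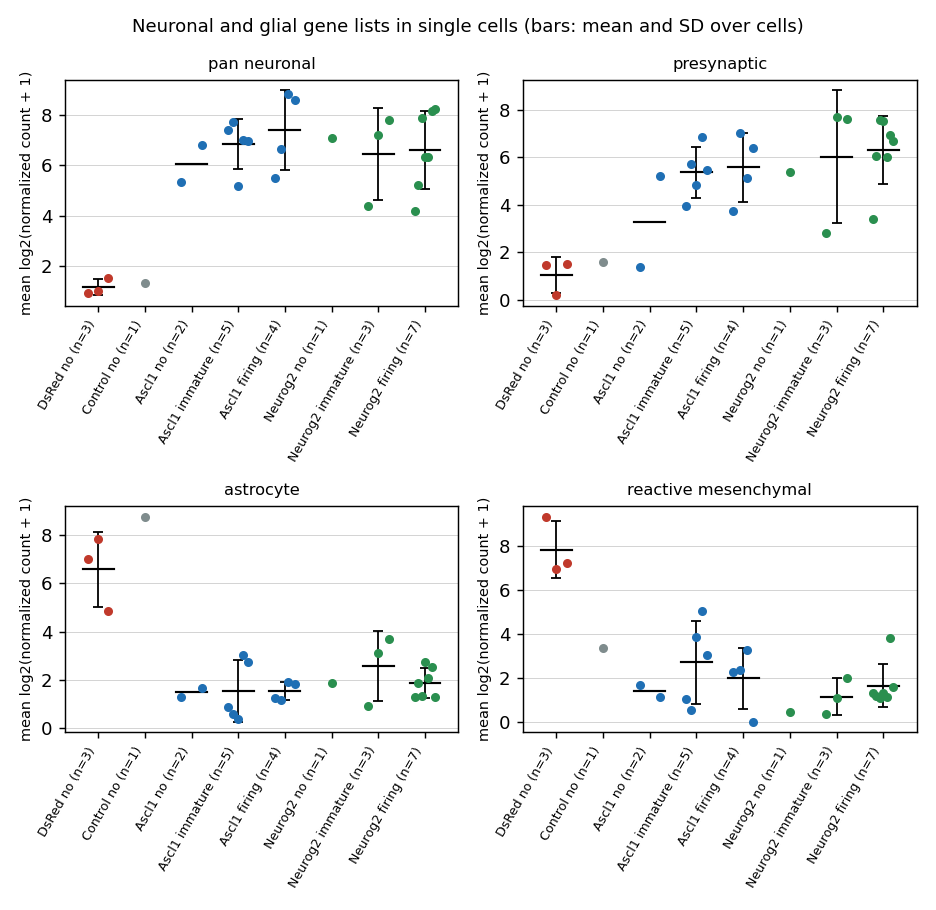
Mean log2(normalized count + 1) of 4 gene lists (y axis) for each cell in the 8 groups of factor and electrophysiological class (x axis, with the number of cells); dots are cells, lines are group means and bars are SDs for groups of more than 2 cells. The pan-neuronal mean is 6.92 in Ascl1 cells and 6.62 in Neurog2 cells against 1.13 in DsRed cells, and the astrocyte scores lie in the opposite order.

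Neurog2 cells were compared with the same 3 DsRed cells, so the results of both factors share their reference and their likeness is not reported. Pan-neuronal genes scored 6.62 ± 1.47 in Neurog2 cells, a difference of 5.49 from DsRed cells, with 18 of 18 members higher. Presynaptic genes scored 6.15 ± 1.69, a difference of 5.10, with 15 of 15 members higher. For both lists 11 of 11 Neurog2 cells lay above every DsRed cell. Snap25 averaged 1948 ± 2250, Tubb3 averaged 650 ± 345, Cplx1 averaged 1098 ± 744, and the synaptic vesicle gene Syp averaged 724 ± 452. Sodium channels scored 3.07 ± 1.36 against 0, with 7 of 9 members higher, where again none could be lower. Scn2b averaged 301 ± 247 and was detected in 9 of 11 Neurog2 cells, and Scn3b averaged 576. The difference was 1.10 for potassium channels, with Kcnc1 at 151. It was 1.07 for calcium channels, within the pooled SD of 1.13, 1.70 for glutamate receptors and 1.11 for GABA and glycine receptors. Gria2 averaged 443 ± 487, Gria3 averaged 76.7 and Glrb averaged 126 ± 178. The percentiles of these channel and receptor lists lay between 97.4 and 100.

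Astrocyte genes scored 2.07 ± 0.87 in Neurog2 cells, a difference of -4.50, with 16 of 19 members lower. Reactive and mesenchymal genes scored 1.40 ± 0.93, a difference of -6.44, with 10 of 11 members lower. Both lists lay at percentile 0 of matched random lists, and each Neurog2 cell scored below every DsRed cell. Gja1 averaged 7.12, Sox9 averaged 24.7 and Vim averaged 81.4 in Neurog2 cells. Stress and immediate early genes differed by -2.79 and ependymal genes by -2.24. Atf3 averaged 4.56, Junb averaged 21.2, and Foxj1 was listed at 0 in all Neurog2 cells.

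Posterior Hox genes, which mark trunk levels of the neural tube, differed by 1.40, with 19 of 24 members higher in Neurog2 cells. That difference was 0.90 when DsRed replicate 3 was left out. The difference was 0.70 for the proneural cascade, 0.06 for V2 interneuron genes, 0.05 for other spinal neuron types, 0.01 for forebrain genes and 0.34 for proliferation genes. It was 0.07 for cholesterol synthesis genes, with Insig1 at 106, -0.40 for oligodendrocyte lineage genes, 0.00 for microglia genes, and 0.01 for vascular and fibroblast genes. It was 0.17 for vesicular glutamate transporters and 0.56 for other transmitters. Of the lists in this paragraph, only the Hox and proliferation genes exceeded the pooled SD. In 3 lists the mean difference and the median member difference had opposite signs. They were -0.05 and 0.59 for GABA and glycine transmission, -0.25 and 0.28 for glycolysis, and 0.09 and -0.29 for mitochondrial transcripts.

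Among 1010 candidates, the largest positive differences between Neurog2 and DsRed cells were those of Cplx1, Snap25, Tubb3, Gng3, Mllt11, Bex2, Rgs17, Acot7, Syp and Neurog2. The G protein subunit gene Gng3 averaged 1425 in Neurog2 cells, and Rgs17, a regulator of G protein signalling, averaged 516 against 0. The largest negative differences were those of C3, Steap4, Ifitm3, Cp, Lcn2, Chil1, Zfp36l1, Sdc4, Hmox1 and Anxa2. C3 averaged 11.1 in Neurog2 cells, a difference of -12.78. Lcn2, which codes for a secreted protein of reactive glia, averaged 39 in Neurog2 cells, 237 ± 575 in Ascl1 cells and 15010 ± 11341 in DsRed cells. Chil1 averaged 0.0446 against 7421 ± 11453 in DsRed cells, where the SD exceeds the mean.

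The Control cell had astrocyte features, while several genes that were high in the DsRed cells were listed at 0. Its score was 8.76 for astrocyte genes, 1.29 for pan-neuronal genes and 1.58 for presynaptic genes. For reactive and mesenchymal genes it scored 3.35, where the DsRed cells scored 9.35, 6.95 and 7.23. Gfap (chr11 102887336 to 102900912, minus strand), the astrocyte intermediate filament gene, stood at 25615 in the Control cell. In DsRed cells it averaged 1234 ± 1241 and was 0 in DsRed replicate 1. C3 stood at 13004 and Vim at 17109 in the Control cell, while Steap4, Cp, Chil1, Hmox1, Hbegf, Tmem100 and Cd44 were listed at 0 and Lcn2 at 2.85. The Control cell also had 924 for Mapt and 365 for Bex2. It is 1 library, in which 3120 genes had a read, against 3886 or more in each DsRed cell. CT010467.1 took 30.9% of its reads, against at most 9.65% in DsRed cells. A listed 0 in this cell does not show that a transcript was lacking.

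When the Control cell was added to the DsRed cells, every named gene of both comparisons kept its direction, and 13 differences became smaller by more than the pooled SD. For Ascl1 the difference was then 7.06 for Mapt, 7.12 for Bex2, -9.05 for Steap4, -8.01 for Hbegf, -7.71 for Cp, -8.45 for Cebpd and -7.84 for Tmem100. For Neurog2 it was 6.91 for Bex2, -8.98 for Steap4, -8.45 for Cp, -8.29 for Lcn2, -8.34 for Chil1 and -8.08 for Hmox1.

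The 3 factor cells of the class no had pan-neuronal scores above those of the DsRed and Control cells. The pan-neuronal score was 5.35 in Ascl1 no replicate 1, 6.80 in Ascl1 no replicate 2 and 7.11 in the Neurog2 no cell. Their astrocyte scores were 1.30, 1.66 and 1.87. The presynaptic score was 5.20 in Ascl1 no replicate 2 and 5.40 in the Neurog2 no cell. In Ascl1 no replicate 1 it was 1.37, within the range of the DsRed and Control cells (0.19 to 1.58).

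Transmitter genes were sparse. The vesicular transporter genes Slc17a6 (chr7 51622006 to 51671119, plus strand), Slc17a8 and Slc32a1 were listed at 0 in all 26 cells. Slc17a7 was detected in 1 Neurog2 immature cell. A listed 0 does not show that a transcript was lacking, because 5 abundant mitochondrial genes (mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) were also listed at 0 in the Ascl1, Neurog2 and DsRed cells. Gad1 or Gad2, which code for the enzymes that make GABA, was detected in 5 of 11 Ascl1 cells (45.5%, 16.7% to 76.6%) and in 4 of 11 Neurog2 cells (36.4%, 10.9% to 69.2%). It was detected in 0 of 3 DsRed cells. With any value above 0 counted, the numbers were 7 of 11 Ascl1, 8 of 11 Neurog2 and 1 of 3 DsRed cells. Because Slc17a6 was listed at 0 throughout, its detection together with a Gad gene could not be assessed.

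Several single genes were counted in both factors' cells. Lhx3 (chr2 26200212 to 26208289, minus strand), a transcription factor gene of V2a interneurons and motor neurons, was detected in 8 of 11 Ascl1 cells (72.7%, 39% to 94%). It was detected in 0 of 11 Neurog2 cells, which by counting error alone allows up to 28.5% of cells at the detection level and does not limit the share of cells expressing it. Its mean was 623 ± 658 in Ascl1 cells and 1.42 ± 1.70 in DsRed cells. Th (chr7 142892752 to 142931128, minus strand), the gene of the enzyme tyrosine hydroxylase, was detected in 4 of 11 Neurog2 cells and in 0 of 11 Ascl1 cells. Its mean was 727 ± 1304 in Neurog2 cells. Slc6a1 (chr6 114282635 to 114317532, plus strand), a GABA transporter gene, was detected in 6 of 11 Ascl1 cells (54.5%, 23.4% to 83.3%), in 1 of 11 Neurog2 cells (9.09%) and in 1 of 3 DsRed cells. Gal was detected in 11 of 11 Ascl1, 8 of 11 Neurog2 and 3 of 3 DsRed cells. It reached 1000 in 9 of 11 Ascl1 cells (81.8%, 48.2% to 97.7%), in 4 of 11 Neurog2 cells and in 0 of 3 DsRed cells. The intervals of both factors overlap for Th, Slc6a1 and Gal. For Lhx3 they do not, but no interval allows for differences between cultures. These genes, with Lhx3, and the levels were picked after their values had been seen.

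**Figure D2:**
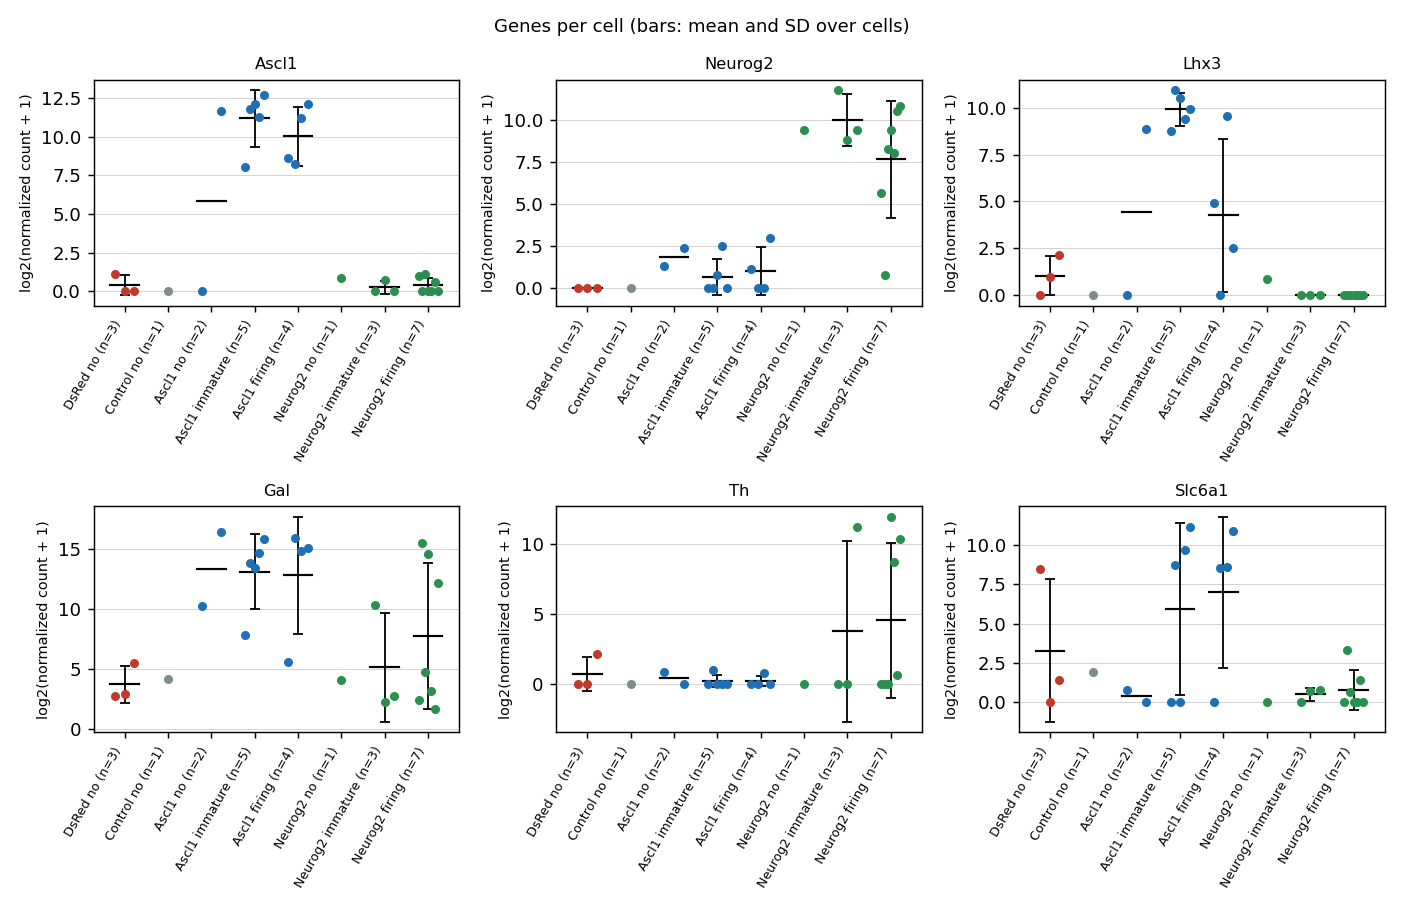
Values of Ascl1, Neurog2, Lhx3, Gal, Th and Slc6a1 as log2(normalized count + 1) (y axis) for each cell in the 8 groups (x axis, with the number of cells); dots are cells, lines are group means and bars are SDs for groups of more than 2 cells. Lhx3 is detected in 8 of 11 Ascl1 cells and in 0 of 11 Neurog2 cells.

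The next comparison addressed whether firing cells made with Ascl1 and with Neurog2 differ. Potassium channels were higher in the 4 Ascl1 firing cells, with a score of 2.38 ± 1.32 against 1.31 ± 0.99 in the 7 Neurog2 firing cells, a difference of 1.06. Kcnma1, a calcium-activated channel gene, averaged 287 ± 192 against 13.8, and Kcnq2 averaged 296 against 65.0. Sodium channels were lower in Ascl1 firing cells, with 1.91 ± 1.5 against 3.17 ± 1.28, a difference of -1.26, and Scn3b averaged 0 against 209. Both differences lay within the pooled SDs of 1.17 and 1.39. The potassium difference rested largely on Ascl1 firing replicate 4, with a score of 4.23 against 1.22 to 2.34 in the other Ascl1 firing cells. The sodium score was lowest in Ascl1 firing replicate 3, at 0.31 against 1.02 to 3.54 in the others.

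Among transmitter and receptor genes, Slc6a1 averaged 656 ± 826 against 1.63 ± 3.40, Th averaged 0.163 against 802 ± 1452, and Gabrb3 averaged 108 against 7.94. Lhx3 averaged 202 ± 381 against 0. Only genes of other spinal neuron types exceeded the pooled SD, with a difference of 0.25 against 0.19. Within it, Pou4f1 differed by 2.80 and was detected in 2 of 4 Ascl1 firing cells and in 1 of 7 Neurog2 firing cells. The difference was 0.79 for pan-neuronal genes, 1.22 for GABA and glycine transmission, 0.54 for GABA and glycine receptors, -0.62 for posterior Hox genes, 0.27 for V2 interneuron genes and 1.48 for cholesterol synthesis genes. For GABA and glycine transmission it rested largely on Ascl1 firing replicate 2. That cell scored 5.55, the other Ascl1 firing cells 0 to 2.17, and the Neurog2 firing mean was 1.14. The mean and the median member difference had opposite signs for presynaptic genes (-0.74 and 0.10), the proneural cascade (0.35 and -0.21), other transmitters (-0.17 and 0.48), oligodendrocyte lineage genes (-0.02 and 0.09) and stress genes (0.01 and -0.56). The remaining lists differed by less than the pooled SD. After the factors themselves, the genes with the largest differences included Nbl1 (712 against 2.87), Gna14 (429 against 0.0702) and Fam110a on the Ascl1 side, out of 2696 candidates. On the Neurog2 side they included Cinp (0 against 212), Sema6d (0 against 169) and Reep1 (4.39 against 455), out of 1172. How large such extremes are between cells of 1 kind was not tested.

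**Figure D3:**
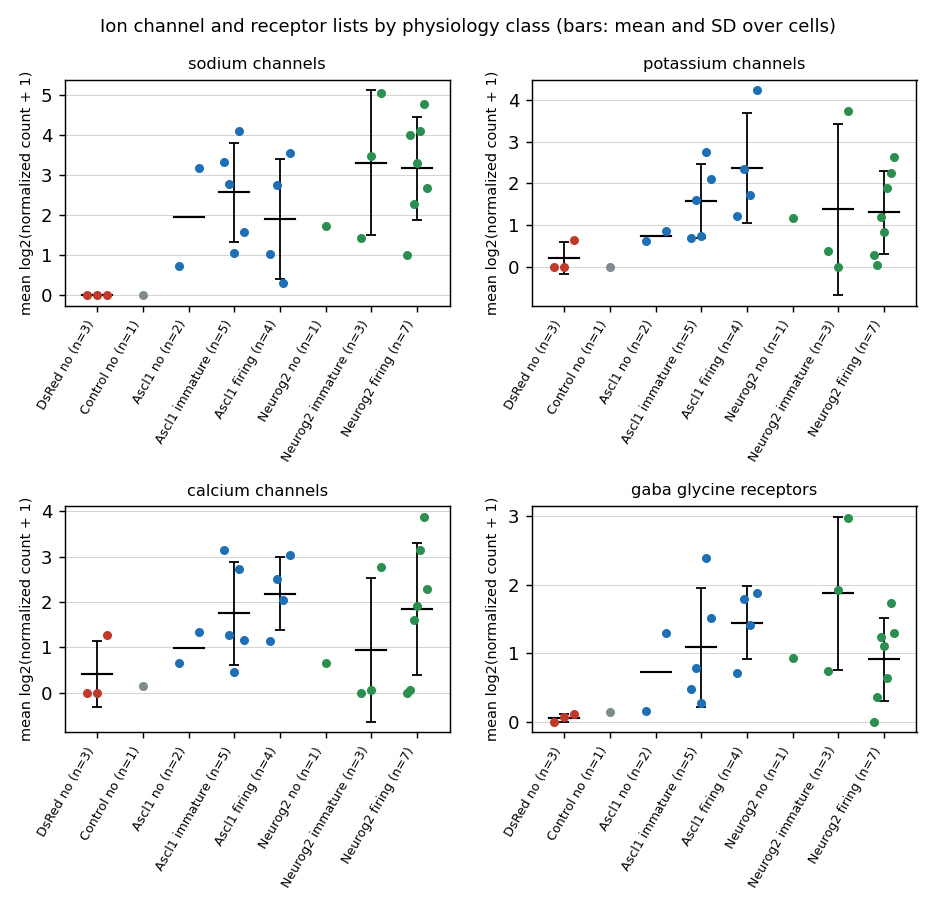
Mean log2(normalized count + 1) of sodium, potassium and calcium channel genes and of GABA and glycine receptor genes (y axis) for each cell in the 8 groups (x axis, with the number of cells); dots are cells, lines are group means and bars are SDs for groups of more than 2 cells. Sodium channel genes are at 0 in the 3 DsRed cells and average 2.22 in Ascl1 and 3.07 in Neurog2 cells.

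Among Ascl1 cells, firing and immature cells were compared to see which genes go with the recorded class. Lhx3 was lower in firing cells, where it averaged 202 and was detected in 2 of 4, than in immature cells, where it averaged 1116 and was detected in 5 of 5. The V2 interneuron score was 0.52 ± 0.40 against 1.01 ± 0.22, a difference of -0.49 that exceeded the pooled SD of 0.32. It was -0.32 when Ascl1 firing replicate 2 was left out. This difference mostly restates Lhx3, whose own log2 difference was -5.67, while 7 of the 12 members were 0 in both groups. Potassium channels differed by 0.79, which rested largely on Ascl1 firing replicate 4. It scored 4.23, the other firing cells 1.22 to 2.34, and the immature mean was 1.58. Kcnq2 averaged 296 with detection in 4 of 4 firing cells against 34.7 with detection in 1 of 5 immature cells. The difference was 0.54 for pan-neuronal genes, -0.66 for sodium channels and -1.13 for cholesterol synthesis genes, all within the pooled SD, as for every other list. The mean and the median member difference had opposite signs for presynaptic genes (0.20 and -0.02) and proliferation genes (-0.02 and 0.00). The genes with the largest differences included Snx15 (332 against 0) and Cadps (389 against 85.5), higher in firing cells, and Apba2 (0 against 586), lower, out of 2696 and 2201 candidates. Cadps codes for a protein that readies dense-core vesicles for release.

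Among Neurog2 cells, GABA and glycine receptor genes were lower in the 7 firing cells than in the 3 immature cells. Their score was 0.91 ± 0.60 against 1.88 ± 1.12, a difference of -0.97 against a pooled SD of 0.90. Gabrb3 averaged 7.94 with detection in 1 of 7 firing cells against 151 ± 118 with detection in 3 of 3 immature cells, and Gabra3 averaged 0 against 110. The difference depended on single cells, at -1.54 without Neurog2 immature replicate 1 and -0.42 without Neurog2 immature replicate 3. Calcium channels differed by 0.90, within the pooled SD, and Cacna2d3 averaged 280 against 0.242. The calcium difference also depended on single cells, as the immature cells scored 0, 0.06 and 2.77. Pan-neuronal genes differed by 0.16, sodium channels by -0.14, potassium channels by -0.07, cholesterol synthesis genes by -1.09 and vesicular glutamate transporters by -0.62. Oligodendrocyte lineage genes differed by 0.38 against a pooled SD of 0.37, and by 0.00 when medians over cells were used. The mean and the median member difference had opposite signs for posterior Hox genes (-0.20 and 0.41), presynaptic genes (0.28 and -0.25), other transmitters (-0.21 and 0.35) and stress genes (0.23 and -0.47). The genes with the largest differences included Tmem246, Pdrg1 and Mbnl1 (278 against 0), higher in firing cells, and Ctu2 (19.6 against 1360), lower, out of 1172 and 807 candidates.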

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

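All tests of explanations in this part were chosen after the values had been seen. In groups of 4 to 10 cells, the highest or lowest cell was compared with the rest by its gap to the nearest cell as a share of the group's range. Of 129 group values checked, 33 exceeded Dixon's 95% value. That value assumes normally distributed values, while these hold many zeros, and lists and single genes overlap. Its usual rate of 1 in 20 therefore does not apply, and the number 33 shows no excess. Where only 1 cell of a group has a value above 0, the share is 1 however low that value is. Values below are log2(normalized count + 1).

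Some of these cells stood apart in neuronal genes. The pan-neuronal score of Ascl1 immature replicate 3 was 5.18, below the range of 7.0 to 7.73 of its group (share 0.711). The presynaptic score of Neurog2 firing replicate 1 was 3.39 against 6.01 to 7.58 (share 0.625), and its stress score was 0 (share 0.647). In that cell 2469 genes had a read. Map2 was 0 in Ascl1 firing replicate 1 against 8.39 to 9.86 (share 0.850). Gal was 5.56 in the same cell against 14.82 to 15.89 (share 0.896).

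Transmitter genes stood apart in single cells. Ascl1 firing replicate 2 alone in its group had Gad1 at 9.25, Gad2 at 6.19 and Slc6a5 at 3.75 (share 1 each). Gad2 was 9.90 in Ascl1 immature replicate 2 (share 0.864). Slc6a1 was 3.35 in Neurog2 firing replicate 2 (share 0.586). Low values of Th were seen in Ascl1 firing replicate 3 and Ascl1 immature replicate 2 (share 1 each). The score for other transmitters was 0.67 in Ascl1 immature replicate 5 (share 0.814). Vsx2 was 4.17 in Ascl1 immature replicate 4 and 0 in the other cells of its group (share 1).

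Glial genes stood apart in further cells. Neurog2 firing replicate 6 had a reactive score of 3.84 against 1.10 to 1.57 (share 0.829) and Gfap at 7.21 (share 0.903). Apoe was 6.51 in Ascl1 firing replicate 4 (share 1) and 6.31 in Neurog2 firing replicate 4 (share 0.909). Aqp4 was 6.24 in Ascl1 immature replicate 4 (share 0.841), 3.14 in Ascl1 firing replicate 3 and 0.70 in Neurog2 firing replicate 4 (share 1 each). Slc1a3 was 1.56 in Ascl1 firing replicate 3 (share 1). The oligodendrocyte score was 1.42 in Ascl1 firing replicate 3 (share 1) and 2.15 in Ascl1 immature replicate 5 (share 0.959). The ependymal score was 1.21 in Ascl1 firing replicate 3 and 0.31 in Neurog2 firing replicate 6 (share 1 each), and 1.57 in Ascl1 immature replicate 4 (share 0.894).

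Of the remaining shares, some belong to lists with values near 0. They were 1 for microglia genes in Ascl1 firing replicate 1, for vascular genes in Ascl1 firing replicate 4 and Neurog2 firing replicate 1, and for forebrain genes in Neurog2 firing replicate 5. In Neurog2 firing replicate 7 the score for proliferation genes was 1.47 against 0 to 0.59 in its group (share 0.597). Its score for other spinal neuron types was 0.36 against 0 to 0.15 (share 0.584). No cause was tested for any single cell named above.

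Lhx3 was detected in Ascl1 cells but in no Neurog2 cell. Deeper sequencing of Ascl1 cells is argued against, since they had fewer reads on average (1.66e+06) than Neurog2 cells (1.79e+06). After all cells were thinned to 700000 reads, 8 Ascl1 and 0 Neurog2 cells had Lhx3 at 5 or more reads per 1000000. Reads spilled over from another library are argued against for 7 cells, which each held more than 10% of the 2019 reads of the highest library, while no cell without Ascl1 as its label held more than 2 reads. For the cell with 48 reads, spill-over cannot be told apart from expression, because that number is small beside the highest library. An effect of Ascl1 itself stays open as a hypothesis, as does a difference between cultures, which the labels do not name.

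In 2 cells the labelled factor was not detected. These cells held at most 2 reads of the other factor, where cells with their factor held at least 102. This argues against a swap between an Ascl1 and a Neurog2 cell that still held its factor. A swap together with loss of the factor's reads cannot be told from these values, because both factors would then be missing. A control cell under a factor label is argued against, since the pan-neuronal scores of the 2 cells were 5.23 and 5.35 against at most 1.5 in DsRed and Control cells. Their astrocyte scores were 1.89 and 1.30 against at least 4.86, although the presynaptic score of Ascl1 no replicate 1 (1.37) lay within the range of the DsRed and Control cells. Loss of transcripts stays open, as the cells had 3013 and 3640 genes with a read, and 3 other factor cells, which held their factor, had fewer genes than the richer of both (2 had fewer than either). A factor that was no longer expressed at the time of collection was not tested.

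DsRed cells had high reactive glial genes and Foxj1, unlike the factor cells. Scaling of the deposited values is argued against, since the reactive difference of Ascl1 from DsRed cells was still -5.05 after rescaling, against a pooled SD of 1.33. Whether microglia were patched in place of astrocytes cannot be told from the 10 microglia genes, which were listed at 0 in DsRed cells. Only 1 of these genes had a value above 0 in any of the 26 cells. The astrocyte genes Gja1 and Aqp4 were detected in 3 of 3 DsRed cells. Other astrocyte genes were not. Slc1a3 stood at 2.36, 11.3 and 0 normalized counts in DsRed replicates 1, 2 and 3, and Gfap was 0 in replicate 1. Mature ependymal cells patched in place of astrocytes stay open, since 2 of the 6 ependymal genes were detected in DsRed cells, and only 3 of the 6 in any cell. A response to culture or to transduction stays open and was not tested, because the labels name no culture and there is only 1 Control cell.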

How the results depend on the processing

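The alternatives gave 3639 values for 252 results. Of these, 3389 stayed within 1 pooled SD of the reported value (counts within 1.5 times), 250 moved further and 0 reversed a difference larger than the pooled SD. Leaving out each cell in turn in groups of up to 5 cells gave 1656 values. Neither this nor leaving out the 2 cells in which few genes had a read can move a difference by 1 pooled SD in groups of these sizes, so that 0 such moves show no stability. Keeping firing cells only moved 0 of 92 values. For Neurog2, where 7 of 11 cells stay, this setting can barely move a difference by 1 pooled SD. Those values therefore show no stability either.

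Of the moved values, most came from the pseudocount (95 for each alternative), which sets the scale of the log. With 0.1 and 10, the difference from DsRed cells was 7.71 and 3.75 for pan-neuronal genes, 3.39 and 1.2 for sodium channels, and -6.61 and -3.48 for astrocyte genes in Ascl1 cells. In Neurog2 cells it was 7.28 and 3.6, 4.49 and 1.77, and -6.02 and -3.06. For single cells, the pan-neuronal score with 0.1 and 10 was 4.0 and 6.82 in Ascl1 no replicate 1, and -1.01 and 3.88 in the Control cell. The astrocyte score was -1.02 and 4.0 in Ascl1 no replicate 1, -0.79 and 4.18 in Ascl1 no replicate 2, and -0.63 and 4.46 in the Neurog2 no cell. The pan-neuronal score of the Control cell was 0.87 after rescaling and 0.92 after thinning. The cause was not tested.

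With only genes of mean 10 or more, the V2 interneuron difference between Ascl1 and Neurog2 firing cells was 1.52 instead of 0.27, since fewer members remain in the list. This setting moved 24 values and kept 194, the most after the pseudocounts. Counting any value above 0 as detection gave 8 Neurog2 cells with Gad1 or Gad2 instead of 4, which follows from the lower level, and moved 4 counts in all. Adding the Control cell moved 13 values and kept 79. Detection at 50 moved 2 counts. Rescaling and thinning moved 6 values each, and the medians over cells moved 4. Leaving out the 2 cells in which the labelled factor was not detected moved 1. It and thinning were chosen after the data had been seen.

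Isoforms could not be compared, because the table has 1 value per gene. No paired analysis was possible, because the labels link no cells of different groups. The number of genes with a read did not follow the reads per cell. It was 8206 in the shallowest library (721017 reads) and 5700 in the deepest (2141987 reads). What limited the detection of genes with few transcripts was not tested.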

Other observations

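Some values belong to no comparison. In the Control cell, Foxj1 stood at 531, Apoe at 16048 and Gal at 17.1 normalized counts, and its ependymal score was 1.51. In Ascl1 no replicate 2, the glycine transporter gene Slc6a5 stood at 552. In Neurog2 firing replicate 2, which held 1 read of Neurog2, Gal stood at 46272. Foxj1 was detected in 3 of 3 DsRed cells and in 0 of 22 factor cells. The summed normalized values differed between groups, with means of 1.19e+06 in Ascl1, 1.22e+06 in Neurog2, 1.91e+06 in DsRed cells and 3.16e+06 in the Control cell.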
